A study of Mus musculus with 16 samples.

How the data were processed

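Gene expression was measured in pancreatic tissue of 16 mice, 4 in each of 4 groups made by crossing 2 genotypes with 2 treatments. Per the labels' protocols, the genotypes were wild type (WT) and Adam17ex/ex, called Adam17ex here, which carries a hypomorphic allele of the gene for the sheddase ADAM17, and the animals were littermates matched for age. Mice received 7 hourly injections of cerulein at 50 µg per kg, an analogue of cholecystokinin that overstimulates acinar cells, or of phosphate-buffered saline (PBS), and were culled 1 h after the last one. The labels give 0 males in the WT PBS group, 1 in the WT cerulein group and 2 in each Adam17ex group. The labels also carry a 4-digit code whose meaning is not given. It runs from 2574 to 2792 in WT PBS and from 1379 to 1394 in WT cerulein, is 1443 and 2373 to 2385 in Adam17ex PBS, and 1685 to 1701 and 2604 in Adam17ex cerulein libraries, so if it orders cohorts, these are not separated from the groups. Xist and Y-linked counts matched the sex label in 16 of 16 libraries.

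Per the labels' protocols, total RNA was isolated from frozen tissue with TRIzol, and 30 ng per sample entered a multiplexed library primed on the poly(A) tail, each sample being indexed and each molecule tagged by a random barcode of 10 bp (unique molecular identifier, UMI), and a sense read of 101 bp was sequenced. The counts deposited by the authors are whole numbers per gene and library, with no normalization, for 24019 genes. The submitters' processing notes name R 4.1.2, edgeR 3.36.0 and limma 3.50.0, and the builds GRCm38 and mm10. The aligner, the counting program and the collapsing of UMIs are not given in the sources used here. Since priming starts at the poly(A) tail, a count reports mostly the 3' end of a transcript, so transcript length has little influence and isoforms that share an end are not told apart. Of the 24019 genes, 23994 had an identifier in GENCODE M21 and 23794 the same start and end there. Near-identical copies (the amylase and trypsin families, Hspa1a and Hspa1b, Hmga1 and Hmga1b, Ceacam1 and Ceacam2, ribosomal protein pseudogenes) can share reads, and values of single members are uncertain for that reason.

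Library depth ranged from 455547 to 1476159 UMIs. In the shallowest library 1 UMI equals 2.20 CPM (the count scaled to the library's total), and in the deepest 0.677. All 24 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.79 to 13.1, so each library counted as 1 replicate.

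The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the groups with its minimum count of 10, which left 8236 genes, and scaled with TMM factors. Quasi-likelihood models (glmQLFit, glmQLFTest) had 1 coefficient per group and sex as a covariate over all 16 libraries, with 11 residual degrees of freedom. Contrasts gave the cerulein effect in each genotype, the genotype effect under each treatment, the interaction and the mean cerulein effect. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold threshold. Values are log2 fold changes ± SE from this fit, and levels are TMM-scaled CPM as mean ± SD with n = 4 unless stated otherwise. On counts simulated from the real means and depths, 60% of 2-fold and 98% of 4-fold changes were recovered for cerulein in WT, 40% and 84% for cerulein in Adam17ex, 44% and 100% for genotype under cerulein, 30% and 90% for genotype under PBS, and 12% and 70% for the interaction. The simulation changed 50 genes at each fold and gave every gene the spread typical of its expression level. Recovery in the real comparisons, where many more genes can change and spread differs by gene, can therefore differ.

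Before the data were examined, 28 gene lists (pathways, cell type markers and stress programmes) were fixed and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists in a comparison. Of their 546 members, 332 were tested, and 24 lists had the 3 tested members that a set test needed. Several genes belong to multiple lists, for example Ier3 and Egr1 to both the ERK target and the immediate early lists. Results of such lists are not independent. A pair of lists of circadian clock genes was added after the data were seen. Genes named in the text follow a rule fixed at the same time. Per comparison it takes the 10 highest and the 10 lowest log2 fold changes among called genes with an official symbol and a mean count of at least 10, and up to 4 members per list with the smallest p. Adam17, Il6, Il6ra, Il6st, Tnf, Egfr, Hbegf, Areg, Reg3b, Amy2a5 and Cpa1 were always included. Not every gene of this selection is named, and some are not reported here. The size of the cerulein response was compared between genotypes by an exact two-sided permutation of genotype within treatment, with 4900 relabellings.

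Other settings tried were RLE and upper-quartile factors, scaling without digestive enzymes, DESeq2 1.42.0, limma-voom, no count filter, a filter at 10 CPM in 4 libraries, a 2-fold threshold, no sex covariate, fits to the compared groups alone, replicate blocks, and leaving out each library. For lists, an estimated correlation and fry were run as well. Runs without the 3 shallow libraries, with counts thinned to equal depth, and with the ribosomal RNA share as a covariate were chosen after seeing the data.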

Results

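Pancreas from WT and Adam17ex mice was profiled by UMI-based RNA sequencing after repeated cerulein or PBS injection, with 4 mice per group. Depth averaged 1031580 UMIs in WT PBS, 1026610 in WT cerulein, 608503 in Adam17ex PBS and 1164390 in Adam17ex cerulein libraries. Replicates 1 to 3 of the Adam17ex PBS group were the shallowest, at 492878, 475952 and 455547 UMIs. In these 3 libraries the ribosomal RNA gene CT010467.1 took 9.02%, 7.84% and 8.08% of UMIs, whereas the other 13 libraries lay between 2.02% and 5.04%. The digestive enzyme list took 38.7% ± 1.10 of UMIs in WT PBS, 31.2% ± 2.42 in WT cerulein, 36.5% ± 4.49 in Adam17ex PBS and 36.4% ± 1.33 in Adam17ex cerulein (SD, n = 4). The first principal component held 43.5% of the variance and the second 11.2%. On the second, Adam17ex PBS replicates 1 to 3 lay at -40.6, -19.2 and -20.8 and replicate 4 at 12.4. WT PBS libraries lay at 14.7 to 26.9, WT cerulein at 4.68 to 18.0 and Adam17ex cerulein at -20.8 to -2.04.

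Adam17 (GRCm38 chromosome 12, 21323509 to 21373632, minus strand) encodes the metalloprotease altered in the mutant. It was counted 41 times in total in WT PBS, 68 times in WT cerulein, 10 times in Adam17ex PBS and 15 times in Adam17ex cerulein libraries. Before TMM scaling these counts were 9.85 ± 3.87, 16.3 ± 5.53, 3.92 ± 2.24 and 3.10 ± 0.722 CPM. Adam17 was lower in Adam17ex under cerulein, by a log2 fold change of -2.05 ± 0.40 (edgeR adjusted p = 0.00138). Under PBS the value was -1.21 ± 0.49, which did not pass (edgeR adjusted p = 0.210). The counts come from the 3' end of the transcript and need not cover the change in the allele, so they do not by themselves check the genotype labels.

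**Figure D1:**
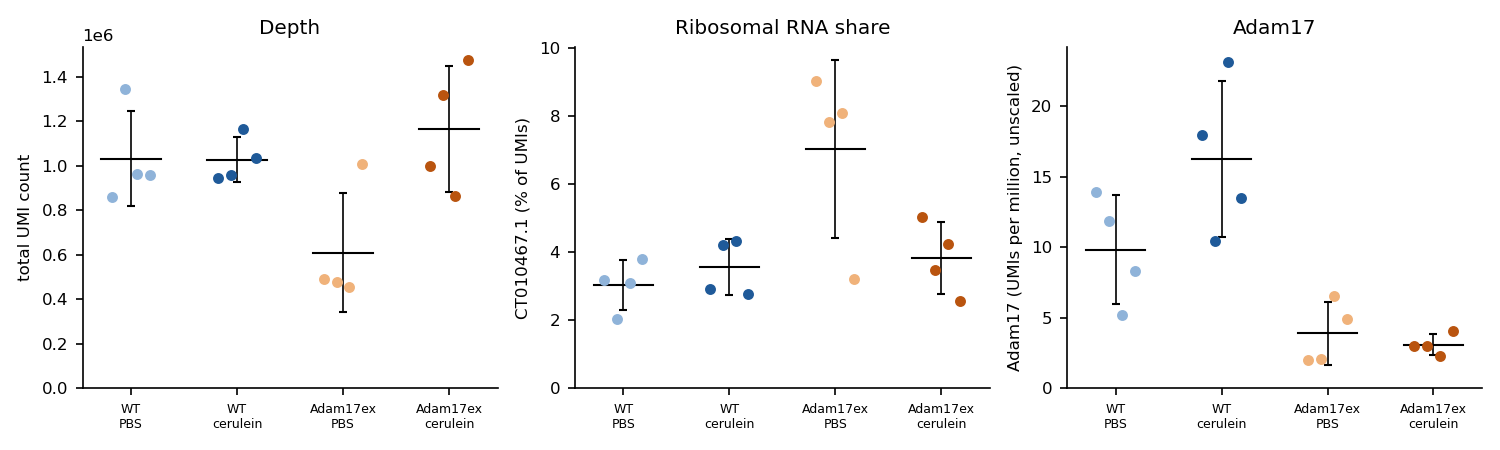
Total UMI count, share of UMIs from the ribosomal RNA gene CT010467.1 in percent, and unscaled Adam17 CPM, with 1 point per library and bars for the mean and SD of 4 libraries per group. The 3 shallow Adam17ex PBS libraries have ribosomal shares of 7.84% to 9.02%, and Adam17 averages 3.10 CPM in Adam17ex and 16.3 CPM in WT cerulein libraries.

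The comparison of cerulein with PBS in WT mice describes the transcriptional response of the normal pancreas to acute pancreatitis. Among keratin genes Krt8 rose by 3.94 ± 0.22, Krt18 by 3.89 ± 0.20 and Krt19 (chromosome 11, 100140810 to 100148665) by 3.42 ± 0.21 on the log2 scale, the last from 51 ± 8.33 to 554 ± 87.3 CPM. The inducible chaperone gene Hspa1b rose by 5.09 ± 0.32 and the actin gene Actg1 by 3.47 ± 0.24. Sel1l, a component of endoplasmic reticulum quality control, fell with a log2 fold change of -3.09 ± 0.27 and the acinar transcription factor gene Bhlha15 (MIST1) with -2.66 ± 0.25. In edgeR's test 3388 of 8236 genes passed, 1631 higher and 1757 lower with cerulein.

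Beside counts of list members, the count adjusted over the list alone is given where it differed. Of the 17 tested members of the duct and metaplasia list, 13 rose and 1 fell (camera adjusted p = 6.52e-13). Cldn4, a tight junction gene, rose by 4.46 ± 0.31 and Epcam by 2.24 ± 0.19. In the heat shock list 11 of 14 members rose, with Hspb1 at 3.77 ± 0.24 and Dnaja1 at 2.27 ± 0.18 (camera adjusted p = 4.57e-12). In the actin cytoskeleton list 17 of 20 rose and 1 (2 adjusted over the list alone) fell, with Tpm4 at 2.73 ± 0.21 and Anxa2 at 2.59 ± 0.23 (camera adjusted p = 1.94e-14). Immediate early genes rose in 12 of 17 cases (13 adjusted over the list alone), among them Ier3 at 3.86 ± 0.37, Junb at 2.90 ± 0.28 and Btg2 at 2.67 ± 0.21 (camera adjusted p = 8.73e-09). Of 16 ADAM17 substrate genes 11 rose and 1 fell, led by the syndecan gene Sdc1 at 3.58 ± 0.18 and with the TNF receptor gene Tnfrsf1a at 1.72 ± 0.23 (camera adjusted p = 8.28e-06). ERK target genes rose in 5 of 9 cases and fell in 1 (camera adjusted p = 0.000130). Cell death and p53 target genes rose in 5 of 8 (6 adjusted over the list alone), with Cdkn1a at 2.77 ± 0.25 and the survival gene Bcl2l1 at 3.05 ± 0.29 (camera adjusted p = 4.29e-05). These 7 lists were also called with an estimated correlation.

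The other list calls in WT were lost when camera used an estimated correlation in place of the preset one. With fry, 15 of the 16 list calls in WT were kept, and the digestive enzyme call was lost (fry adjusted p = 0.05004). IL-6/STAT3 and acute phase genes rose in 11 of 21 cases and fell in 3 (4 adjusted over the list alone), with Lcn2 (lipocalin 2) at 3.92 ± 0.41 and Cebpd at 3.54 ± 0.43 (camera adjusted p = 0.000217, and adjusted p = 0.151 with an estimated correlation). Reg3b of this list stood at a log2 CPM of 11.18 in WT PBS replicate 2, against 7.20 to 7.77 in the rest of that group. The list was still called without that library. NF-kB target genes rose in 6 of 11 cases (7 adjusted over the list alone), with Relb at 3.07 ± 0.39 and the chemokine gene Ccl7 at 2.93 ± 0.61 (camera adjusted p = 0.000825, and adjusted p = 0.148 with an estimated correlation). In the oxidative stress list 8 of 17 rose and 5 fell, with the metallothionein gene Mt2 at 3.41 ± 0.27 and Srxn1 at 4.30 ± 0.37 (camera adjusted p = 0.00669, and adjusted p = 0.0534 with an estimated correlation). Ribosome biogenesis genes rose in 9 of 19 cases (camera adjusted p = 0.00298, and adjusted p = 0.280 with an estimated correlation). The autophagy and lysosome list had 8 of 19 higher and 3 (4 adjusted over the list alone) lower, with a median of -0.02 although its mean was 0.36 and the test pointed up (camera adjusted p = 0.0400, and adjusted p = 0.220 with an estimated correlation).

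Unfolded protein response genes fell in 14 of 25 cases (15 adjusted over the list alone) and rose in 3, with Dnajb11 at -2.38 ± 0.20 and Creld2 at -2.72 ± 0.24 (camera adjusted p = 2.22e-06, and adjusted p = 0.0946 with an estimated correlation). Of 28 digestive enzyme genes 11 fell and 2 rose (camera adjusted p = 0.0253, and adjusted p = 0.710 with an estimated correlation). Colipase, Clps, fell with a log2 fold change of -1.55 ± 0.22 and pancreatic ribonuclease, Rnase1, with -1.68 ± 0.22, whereas the trypsinogen genes Prss1 and Prss3, whose reads near-identical family members can share, rose by 2.29 ± 0.30 and 2.23 ± 0.40. Carboxypeptidase A1, Cpa1, fell with -0.89 ± 0.22, and the amylase gene Amy2a5 had -0.49 ± 0.23 (edgeR adjusted p = 0.0948). The enzyme call was lost without WT PBS replicate 4 (median -0.30) or WT cerulein replicate 3 (-0.32), and the autophagy call without WT PBS replicate 1 (0.05) or 4 (-0.04). Mitochondrially encoded transcripts fell in 10 of 11 cases (11 adjusted over the list alone) (camera adjusted p = 0.00298, and adjusted p = 0.384 with an estimated correlation). Adipocyte markers fell in all 7 tested cases, with Cfd (adipsin) at -4.80 ± 1.17 (camera adjusted p = 0.00630, and adjusted p = 0.390 with an estimated correlation). All 5 tested B and plasma cell markers fell, Ighm with -5.07 ± 1.06, although the list did not pass (camera adjusted p = 0.0930). In WT PBS replicates 1 to 4 the B cell list had a mean log2 CPM of 6.02, 7.01, 2.60 and 2.75, against 1.67 to 2.86 with cerulein, and the adipocyte list at least 5.49 in replicates 1 and 2 and at most 3.95 in replicates 3 and 4, against 2.23 to 3.04.

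Among the named genes in WT, the largest rises included Slc26a9, an anion transporter gene, at 5.17 ± 0.33, the chromatin gene Hmga1 at 4.96 ± 0.34, Gprc5a at 4.78 ± 0.67 and Bcl3, a member of the IL-6/STAT3 list, at 4.65 ± 0.69. Nrip3 had 0 counts in the 4 WT PBS libraries and 80 in the 4 cerulein libraries, at least 22.9-fold higher against a floor of 3 counts over the group. Large falls included P2ry14 at -4.50 ± 0.44, A1cf at -4.62 ± 0.50, Nat8 at -4.46 ± 0.46 and the transcription factor gene Foxp2 at -4.32 ± 0.48. The acinar transcription factor gene Rbpjl fell with -1.48 ± 0.29 while Ptf1a rose by 0.93 ± 0.20. Among the pathway genes of interest Egfr rose by 2.17 ± 0.27, Il6st (gp130) by 0.76 ± 0.21 and Hbegf by 1.32 ± 0.36, whereas Il6ra fell with -0.62 ± 0.24, a call lost in 17 of 23 alternatives. Il6 was counted 1 time in the WT PBS and 3 times in the WT cerulein libraries, and Tnf 1 and 2 times, too few for a test. All 4 cerulein libraries lay beyond all 4 PBS libraries in 2854 of the 3388 called genes, 84.2%. These genes were called on the same libraries, so a high share follows largely from the selection. Thinned to equal depth, 2090 genes were called, with fewer genes left to test.

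The same comparison in Adam17ex mice asks how the pancreas with the hypomorphic allele responds. The calcineurin feedback gene Rcan1 showed the largest rise of a named gene, 5.55 ± 0.23, from 15.5 ± 2.56 to 728 ± 88.5 CPM. Ier3 rose by 4.50 ± 0.41, Egr1 by 3.69 ± 0.34 and Hbegf, which encodes an EGF receptor ligand released by ADAM17, by 3.98 ± 0.35. Krt8 rose by 2.71 ± 0.21 and Krt18 by 2.10 ± 0.19. The circadian output genes Dbp and Tef fell with -4.89 ± 0.43 and -4.64 ± 0.32. In edgeR's test 2493 genes passed, 1162 higher and 1331 lower.

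Immediate early genes rose in 13 of 17 cases (14 adjusted over the list alone), with Klf6 at 2.13 ± 0.24 (camera adjusted p = 1.22e-15). ADAM17 substrate genes rose in 11 of 16 cases and fell in 2, with Sdc1 at 3.16 ± 0.22 (camera adjusted p = 1.89e-06). The duct and metaplasia list had 8 of 17 higher and 1 (2 adjusted over the list alone) lower, with Krt19 at 1.34 ± 0.21 (camera adjusted p = 9.46e-05). ERK targets had 5 of 9 higher and 1 lower (camera adjusted p = 0.000383). Cell death and p53 targets rose in 5 of 8 cases, with Cdkn1a at 2.76 ± 0.28 (camera adjusted p = 9.46e-05). Oxidative stress genes rose in 7 of 17 (8 adjusted over the list alone) and fell in 2 (3 adjusted over the list alone), with Mt2 at 2.33 ± 0.25 (camera adjusted p = 0.00385). These 6 lists were also called with an estimated correlation. Actin genes rose in 13 of 20 cases (15 adjusted over the list alone) and fell in 1, with Actg1 at 1.74 ± 0.23 (camera adjusted p = 1.96e-07, and adjusted p = 0.103 with an estimated correlation). IL-6/STAT3 genes rose in 13 of 21 cases and fell in 1, with Lcn2 at 2.97 ± 0.50 and Reg3b, a secreted lectin of the injured pancreas, at 2.11 ± 0.66 (camera adjusted p = 1.89e-06, and adjusted p = 0.103 with an estimated correlation). Heat shock genes rose in 7 of 14 cases (9 adjusted over the list alone) and fell in 1, with Hspb1 at 1.61 ± 0.27 (camera adjusted p = 0.0235, and adjusted p = 0.282 with an estimated correlation).

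Ribosome biogenesis genes rose in 9 of 19 cases (10 adjusted over the list alone), NF-kB targets in 3 of 11, and mitochondrial transcripts fell in 9 of 11 (10 adjusted over the list alone) (camera adjusted p = 0.000683, 0.0367 and 0.000383, with adjusted p = 0.294, 0.408 and 0.319 with an estimated correlation). The unfolded protein response list was split, with 9 of 25 higher and 7 (9 adjusted over the list alone) lower, a median of -0.22 and a mean of 0.25, and did not pass (camera adjusted p = 0.669). Within it the stress effectors Atf3, Trib3 and Atf4 rose by 3.37 ± 0.45, 2.59 ± 0.33 and 1.11 ± 0.20, while Sel1l fell with -1.78 ± 0.25. Islet markers fell in 11 of 15 cases (12 adjusted over the list alone), with Ins2 at -1.87 ± 0.49, and fibroblast and stellate markers in 8 of 12 (9 adjusted over the list alone), with Dcn (decorin) at -1.08 ± 0.26 (camera adjusted p = 0.000566 and 0.00514, both with adjusted p = 0.408 with an estimated correlation). Monocyte and macrophage markers fell in 5 of 10 cases (7 adjusted over the list alone), with Csf1r at -2.75 ± 0.62, adipocyte markers in 6 of 7 and B and plasma cell markers in 4 of 5 (5 adjusted over the list alone) (camera adjusted p = 0.0367, 0.00161 and 0.0357, with adjusted p = 0.528, 0.341 and 0.408 with an estimated correlation). In Adam17ex cerulein replicate 3 the adipocyte list had a mean log2 CPM of 5.81, against 3.14 to 3.21 in the other 3, and the B cell list 4.51, against 1.79 to 2.17. The B cell list had 2.67, 4.36, 6.66 and 5.98 in Adam17ex PBS replicates 1 to 4. The monocyte list had 6.39 in Adam17ex PBS replicate 3, whose enzyme share was 29.8%, against 3.71 to 4.76. Without that library the monocyte, fibroblast and B cell calls were lost (medians -0.56, -0.54 and -2.37), as was the monocyte call without Adam17ex cerulein replicate 2 (-1.32). The NF-kB call was lost without Adam17ex PBS replicate 1 (0.69) or 4 (0.65) or Adam17ex cerulein replicate 1 (0.81). The PBS reference holds the 3 shallow libraries with a high ribosomal share, and without these 3 the islet list had a median of 0.23 in place of -1.85. Without the 3 libraries 1360 genes were called, 1132 of them among the 2493, in a fit that takes the lone remaining Adam17ex PBS library to vary like the other groups.

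**Figure D2:**
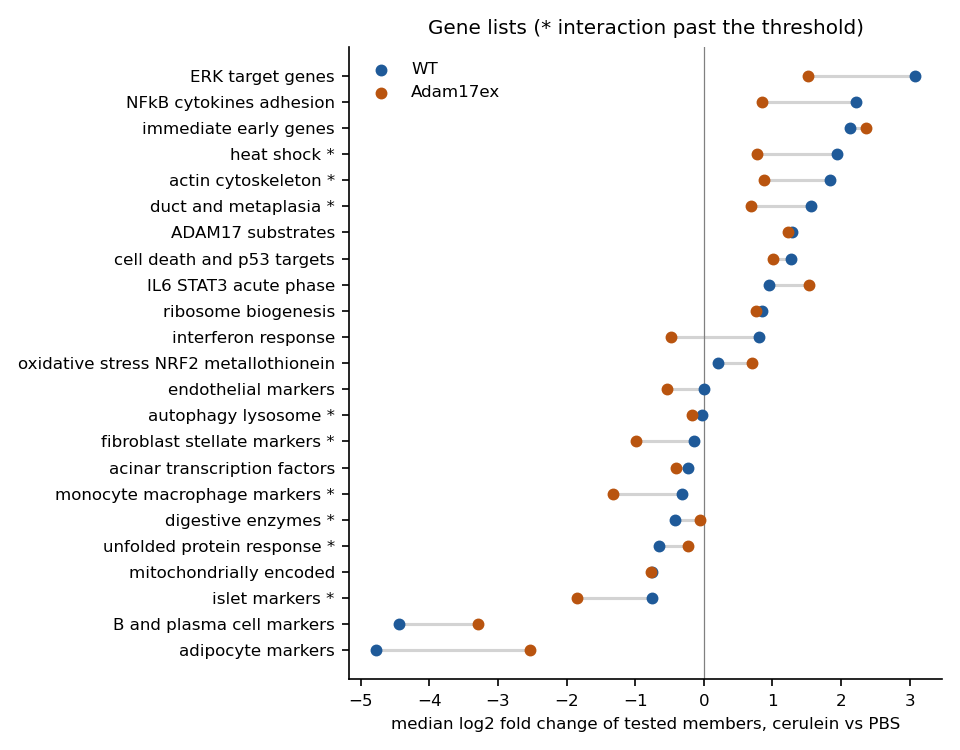
Median log2 fold change of cerulein against PBS over the tested members of each gene list, with blue points for WT and orange points for Adam17ex, and an asterisk where the interaction passed. The heat shock list has a median of 1.94 in WT and 0.77 in Adam17ex, and the duct and metaplasia list 1.56 and 0.69.

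Adam17ex and WT mice were compared under cerulein to see which parts of the injured state depend on genotype. Among single genes that rose in WT, Hspa1b (chromosome 17, 34956436 to 34959238) was lower in Adam17ex, with a log2 fold change of -4.11 ± 0.31, as were Cldn4 at -3.98 ± 0.28, Hmga1 at -3.61 ± 0.29 and Krt19 at -1.89 ± 0.19. Ceacam1, an epithelial adhesion gene, had 209 ± 57.6 CPM in WT and 23 ± 2.53 in Adam17ex. In the other direction Fgf21, a secreted stress hormone (chromosome 7, 45613886 to 45615490), was higher in Adam17ex by 5.40 ± 0.47, Rcan1 by 2.81 ± 0.18 and Hbegf by 2.86 ± 0.27. In edgeR's test 799 genes passed, 482 higher and 317 lower in Adam17ex. In 710 of them (88.9%) all 4 libraries lay beyond all 4 of WT, a share that follows largely from calling genes on these same libraries.

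Heat shock genes were lower in 10 of 14 cases (11 adjusted over the list alone) and higher in 0 (1 adjusted over the list alone), with Hspb1 at -2.25 ± 0.22 (camera adjusted p = 8.81e-20). Duct and metaplasia genes were lower in 11 of 17 cases (12 adjusted over the list alone) and higher in 2, with Krt18 at -1.22 ± 0.18, Epcam at -1.16 ± 0.17 and osteopontin, Spp1, at -1.78 ± 0.22 (camera adjusted p = 3.75e-11). Both lists were also called with an estimated correlation. Actin genes were lower in 5 of 20 cases (9 adjusted over the list alone) and higher in 0 (1 adjusted over the list alone), with Actg1 at -1.27 ± 0.22 and Anxa2 at -1.30 ± 0.22 (camera adjusted p = 4.56e-05, and adjusted p = 0.464 with an estimated correlation). Unfolded protein response genes were higher in 13 of 25 cases (15 adjusted over the list alone), with Herpud1 at 1.75 ± 0.29, Trib3 at 2.27 ± 0.27 and Atf4 at 1.12 ± 0.20 (camera adjusted p = 5.93e-10, and adjusted p = 0.0503 with an estimated correlation). Immediate early genes were higher in 10 of 17 cases (11 adjusted over the list alone), with Klf6 at 1.66 ± 0.23 and Egr1 at 1.76 ± 0.25 (camera adjusted p = 1.03e-07, and adjusted p = 0.0503 with an estimated correlation). Digestive enzymes were higher in 7 of 28 cases (10 adjusted over the list alone), with Clps at 1.09 ± 0.22 and Rnase1 at 1.24 ± 0.22 (camera adjusted p = 2.47e-05, and adjusted p = 0.617 with an estimated correlation).

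ADAM17 substrate genes did not move together, with 2 (3 adjusted over the list alone) higher and 2 (3 adjusted over the list alone) lower of 16 (camera adjusted p = 0.659). Neither did the IL-6/STAT3 list, with 4 higher and 0 (1 adjusted over the list alone) lower of 21 (camera adjusted p = 0.452), or the ERK list (camera adjusted p = 0.897). Il6st had 0.08 ± 0.20 (edgeR adjusted p = 0.846), Egfr -0.17 ± 0.22 (edgeR adjusted p = 0.698) and Reg3b 0.05 ± 0.64 (edgeR adjusted p = 0.974), none of which passed. Further genes higher in Adam17ex were Pkdcc at 3.13 ± 0.28, the phosphatase gene Dusp8 at 2.84 ± 0.38, B4galt4 at 2.47 ± 0.34, Nedd9 at 2.56 ± 0.34 and the T cell receptor constant gene Trbc1 at 3.07 ± 0.43. Trbc1 was the single tested member of the T and NK cell list, with 7.29 ± 4.54 CPM in WT and 73.5 ± 36.7 in Adam17ex cerulein libraries. The other markers of that list were too low to test and together were not higher in Adam17ex. Further genes lower in Adam17ex were Slc26a9 at -3.02 ± 0.26, Gprc5a at -3.53 ± 0.52 and the interferon response factor gene Irf1 at -2.14 ± 0.45. Without WT cerulein replicate 1, 402 genes were called, and 419 in counts thinned to equal depth.

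**Figure D3:**
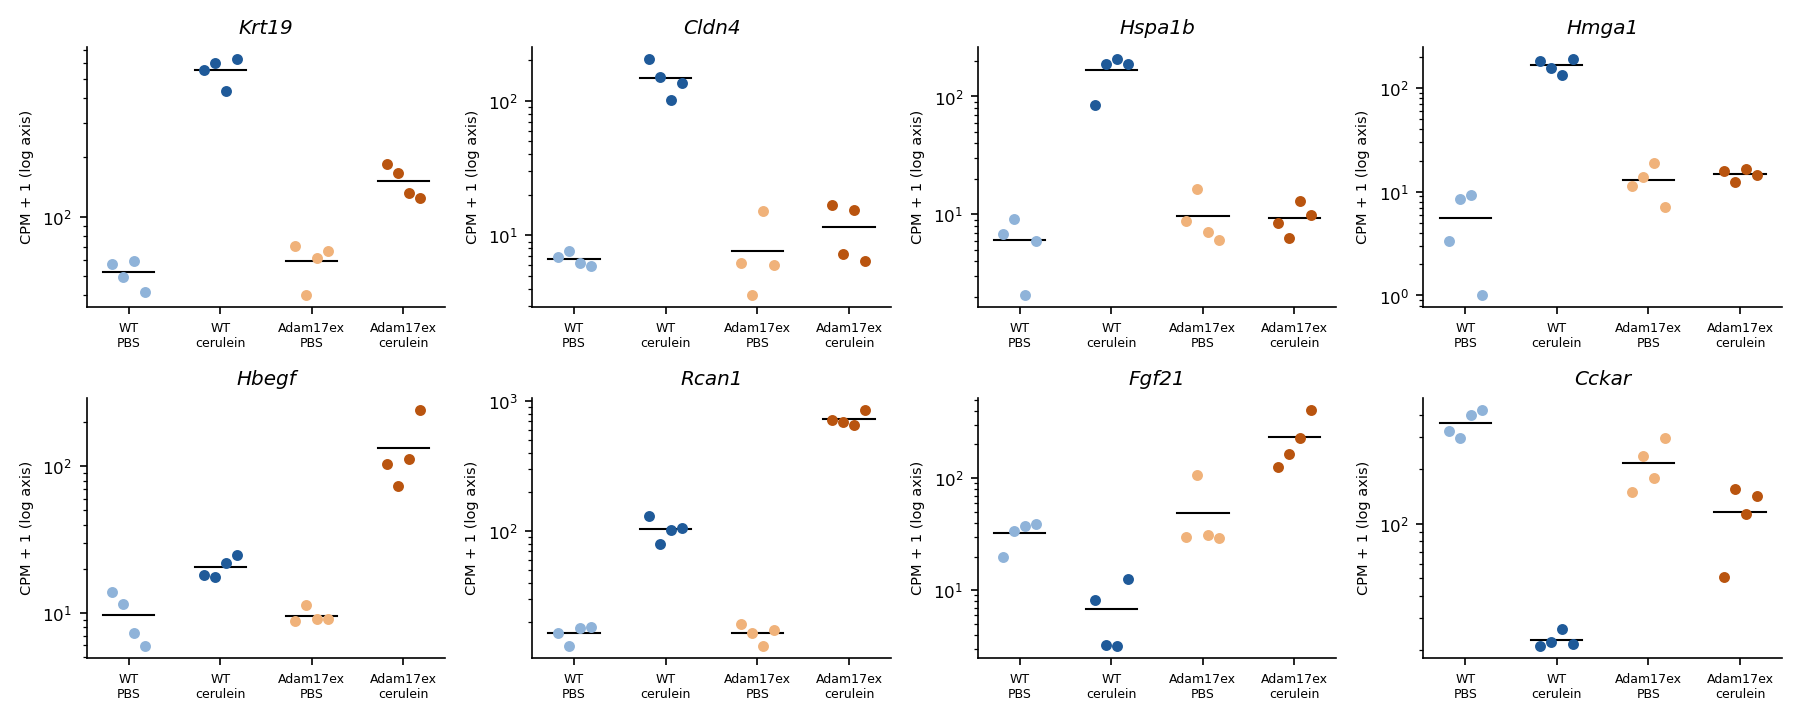
TMM-scaled CPM plus 1 on a log axis for 8 genes, with 1 point per library and a line at the mean of 4 libraries per group. Krt19, Cldn4, Hspa1b and Hmga1 are highest in WT cerulein libraries, and Hbegf, Rcan1 and Fgf21 are highest in Adam17ex cerulein libraries.

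Under PBS the genotypes were compared to see how the uninjured pancreas differs. Among the named genes the circadian clock gene Dbp had the largest rise: it (chromosome 7, 45705088 to 45710203) had 3.81 ± 4.03 CPM in WT and 76.7 ± 23 CPM in Adam17ex (4.53 ± 0.44), Nr1d2 was higher by 2.77 ± 0.38, and Cry1 was lower, with a log2 fold change of -1.83 ± 0.37. The collagen genes Col6a1 and Col6a2 were higher in Adam17ex by 2.08 ± 0.36 and 1.88 ± 0.41, and Sparc by 1.32 ± 0.33. Metallothionein Mt2 was higher by 1.63 ± 0.27 and the zinc transporter gene Slc30a2 by 2.16 ± 0.34. In edgeR's test 112 genes passed, 52 higher and 60 lower, which is 1.36% of the genes tested.

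Fibroblast and stellate markers were higher in 4 of 12 cases (9 adjusted over the list alone), with Rgs5 at 1.32 ± 0.29 and Gsn at 0.94 ± 0.21 (camera adjusted p = 1.13e-10, and adjusted p = 0.235 with an estimated correlation). Endothelial markers had a median of 0.82 with 0 of 8 (3 adjusted over the list alone) called, and monocyte and macrophage markers 0.87 with 0 of 10 called (camera adjusted p = 0.00191 and 0.0147, with adjusted p = 0.235 and 0.709 with an estimated correlation). Unfolded protein response genes were lower in 2 of 25 cases (7 adjusted over the list alone) and higher in 0 (1 adjusted over the list alone), with Creld2 at -1.48 ± 0.26 and Dnajb11 at -0.91 ± 0.21 (camera adjusted p = 0.000225, and adjusted p = 0.304 with an estimated correlation). Immediate early genes had 1 of 17 (5 adjusted over the list alone) called, Jun at 1.68 ± 0.41, and actin genes 0 of 20 (camera adjusted p = 0.00124 and 0.0439, with adjusted p = 0.304 and 0.727 with an estimated correlation). Digestive enzymes had a median of -0.00 with 0 of 28 called (camera adjusted p = 0.870). The ribosomal RNA share was 7.03% ± 2.61 in Adam17ex and 3.02% ± 0.736 in WT PBS libraries (SD, n = 4). With the ribosomal share as a covariate 21 genes were called, 17 of them among the 112, and without the 3 shallow Adam17ex libraries 15, 9 of them among the 112. Leaving out any 1 of the 8 libraries gave between 30 (without WT replicate 3) and 370 genes (without Adam17ex replicate 4), a fit without sex 406, and a fit to these 8 libraries alone 14. Without the 3 shallow libraries, which leaves replicate 4 as the single Adam17ex PBS library, the endothelial, monocyte, immediate early and actin list calls were lost. Their medians were 0.42, 0.36, 0.14 and 0.24, so a smaller change and lost power are not separated. Adam17ex PBS replicate 3, with an enzyme share of 29.8%, stood at a mean log2 CPM of 6.39 for the monocyte and 6.27 for the actin list, against 3.71 to 4.76 and 5.34 to 5.66 in the other 3, and without it both calls were lost (medians 0.25 and 0.12). Both were also lost without WT PBS replicate 3 (0.63 and 0.27) or 4 (0.62 and 0.28), and the actin call without Adam17ex PBS replicate 4 (0.29). Among the genes named above, Dbp, Nr1d2, Mt2 and Slc30a2 were called in every alternative run. Creld2 was called in 22 of 23, Cry1 in 18 of 22, Col6a1 in 18 of 21, Rgs5 in 15 of 23, Sparc in 14 of 23, Col6a2 in 13 of 21, and Gsn, Jun and Dnajb11 in 13 of 23.

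**Figure D4:**
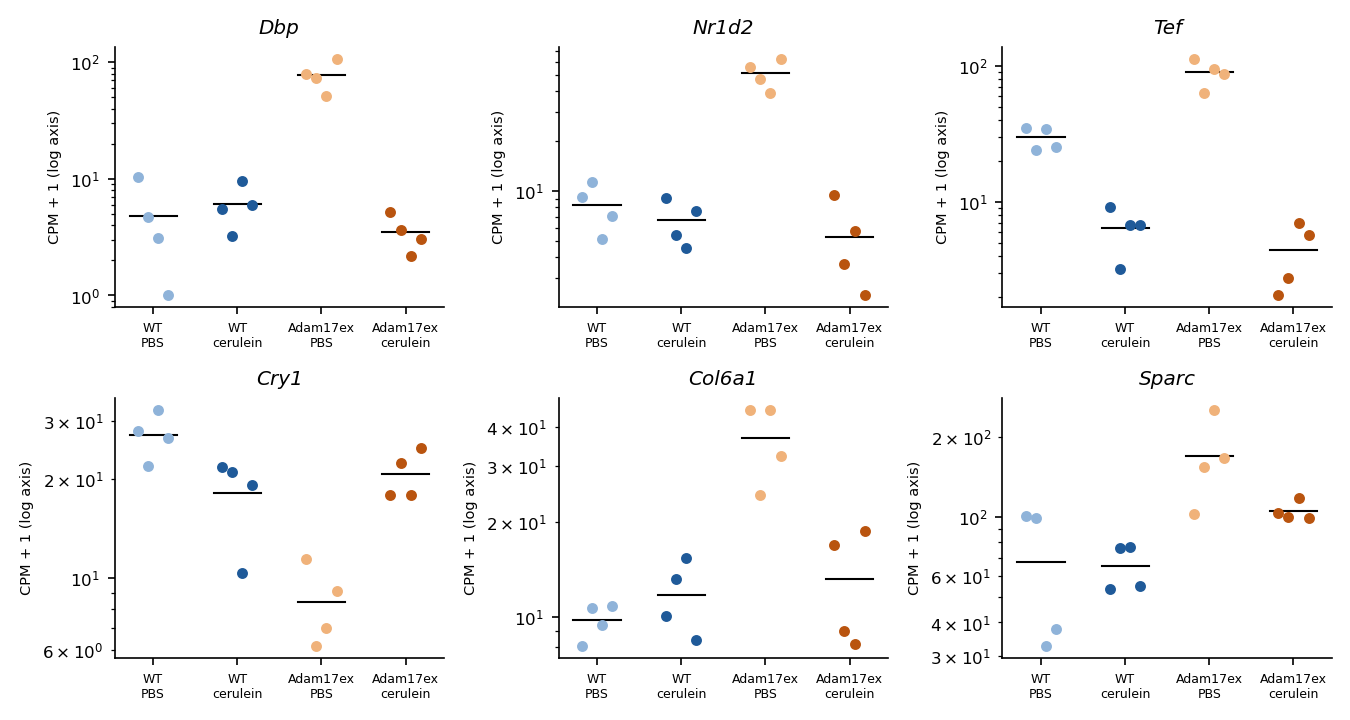
TMM-scaled CPM plus 1 on a log axis for 4 clock genes, Col6a1 and Sparc, with 1 point per library and a line at the mean of 4 libraries per group. Dbp, Nr1d2 and Tef are highest in Adam17ex PBS libraries, in which Cry1 is lowest and Col6a1 and Sparc are highest by their means.

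The interaction tests whether the cerulein effect itself differed between genotypes. Hspa1b (-4.94), Hmga1 (-4.64), Cldn4 (-3.92), Slc26a9 (-3.54) and Krt19 (-2.08) responded less in Adam17ex, in log2 units of Adam17ex effect minus WT effect. Fgf21 (4.67), Pkdcc (3.77) and Hbegf (2.67) had interactions above 0. Cckar (chromosome 5, 53697776 to 53707705), the receptor through which cerulein acts, fell from 361 ± 59.6 to 21.7 ± 2.32 CPM in WT and from 215 ± 65.5 to 114 ± 46.8 CPM in Adam17ex, an interaction of 3.12 ± 0.39 (edgeR adjusted p = 5.16e-05). In edgeR's test 496 genes passed, 309 above 0 and 187 below.

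Unfolded protein response genes had 13 of 25 (16 adjusted over the list alone) interactions above 0, with Dnajb9 at 1.86 ± 0.34 and Creld2 at 1.88 ± 0.35 (camera adjusted p = 6.57e-13). Heat shock and duct lists had 7 of 14 (9 adjusted over the list alone) and 7 of 17 (10 adjusted over the list alone) below 0, and 0 and 0 (1 adjusted over the list alone) above 0, with Hspb1 at -2.16 ± 0.37 and Krt18 at -1.78 ± 0.26 (camera adjusted p = 5.69e-09 and 6.41e-08). These 3 lists were also called with an estimated correlation. Actin genes had 6 of 20 (9 adjusted over the list alone) below 0, with Anxa2 at -1.98 ± 0.33, and autophagy genes 5 of 19 (camera adjusted p = 3.42e-06 and 0.0116, both with adjusted p = 0.305 with an estimated correlation). Digestive enzymes had 3 of 28 above 0, with Clps at 1.21 ± 0.31 (camera adjusted p = 0.000259, and adjusted p = 0.606 with an estimated correlation). Fibroblast, monocyte and islet lists were below 0 with 1 (2 adjusted over the list alone), 0 and 0 called members (camera adjusted p = 0.0114, 0.0114 and 0.0448, with adjusted p = 0.606, 0.606 and 0.732 with an estimated correlation). The islet list turned to a median of 1.10 without the 3 shallow Adam17ex PBS libraries and 0.70 with the ribosomal share as a covariate, in place of -0.99. Its call held only without WT PBS or cerulein replicate 1, Adam17ex PBS replicate 4 or Adam17ex cerulein replicate 3 or 4, among the runs leaving out 1 library. The fibroblast and monocyte calls were lost without Adam17ex PBS replicate 3 (medians -0.38 and -0.37), and the fibroblast call without WT PBS replicate 3 (-0.41) or WT cerulein replicate 2 (-0.55) or 3 (-0.55). The autophagy call was lost without Adam17ex PBS replicate 4 (-0.16). The clock genes Dbp and Nr1d2, at -5.48 and -3.26, also differed between genotypes under PBS. Without the 3 shallow libraries 152 genes passed, 121 of them among the 496. Leaving out Adam17ex cerulein replicate 2 gave 239, Adam17ex cerulein replicate 3 gave 314 and WT cerulein replicate 3 gave 322.

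Across genes, which are not independent replicates, the log2 effects of cerulein in both genotypes had a Pearson correlation of 0.694 and a Spearman correlation of 0.654 over 8236 genes, and these contrasts share no library. Of the called genes, 743 were higher in both genotypes and 852 lower in both, where independent lists would share 230 and 284, and 44 were called in opposite directions. The mean effect over both genotypes called 3989 genes, 1895 higher and 2094 lower. Over these genes the median response was 0.98 in WT and 0.79 in Adam17ex on the log2 scale. The median difference was -0.18, and 2443 of 3989 genes (61.2%) responded less in Adam17ex (exact two-sided permutation p = 0.0139, n = 4 per group). Of 327 genes called for the mean effect and for the interaction, 264 responded less in Adam17ex, 108 with a smaller rise and 156 with a smaller fall, and 63 responded more. Both comparisons also carry the genotype difference under PBS, where 3 Adam17ex libraries are shallow. A smaller response is therefore not separated from a different PBS level, and the permutation was not repeated without these 3 libraries together.

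**Figure D5:**
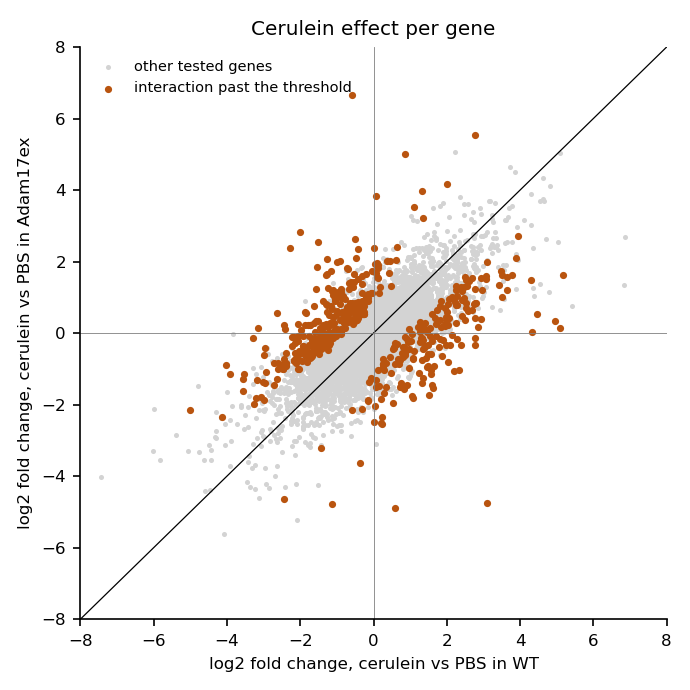
Log2 fold change of cerulein against PBS per tested gene, in WT on the horizontal and in Adam17ex on the vertical axis, with the line of equal effects and the genes past the interaction threshold in orange. The Pearson correlation over the 8236 genes is 0.694, and 496 genes are in orange.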

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

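Among the tests below, a constant genotype effect and time of day for the clock genes, a uniformly smaller response and time since injection for the cerulein difference, and the acinar share for the marker lists were chosen only after the result was seen. The same holds for the clock gene lists themselves.

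The interaction called 496 genes and 9 gene lists, which is a tested difference between the genotypes' cerulein effects. With an estimated correlation 3 lists were called, the unfolded protein response, heat shock and duct lists. The actin and autophagy lists then had adjusted p = 0.305, the enzyme, fibroblast and monocyte lists 0.606 and the islet list 0.732. The islet median was 1.10 without the 3 shallow libraries in place of -0.99. The log2 interactions of single genes were -4.94 for Hspa1b, -4.64 for Hmga1, -4.30 for Hmga1b, -3.92 for Cldn4, -3.54 for Slc26a9, -3.25 for Gadd45g, -3.18 for Irf1, -5.48 for Dbp and -3.26 for Nr1d2. Above 0 they were 4.67 for Fgf21, 3.77 for Pkdcc, 3.34 for B4galt4, 3.12 for Cckar and 4.86 for the ribosomal pseudogene Rps15a-ps2, whose reads its parent gene can share. Nfil3 had a fitted 4.15, against an Adam17ex PBS group with 2 counts.

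Clock genes differed between genotypes under PBS in opposite directions. In counts thinned to equal depth the 4 output genes still tested had a median log2 fold change of 2.28, against 2.32 at full depth. Random thinning keeps the ratios of scaled counts on average. It therefore tests only how the fit handles unequal depth, not what else sets the shallow libraries apart. Under cerulein the 8 output genes had a median of -0.46, which argues against a genotype effect that is the same under both treatments. Genes of the opposite phase had a median of -1.83 under PBS, against 2.69 for the output genes, as tissue collected at another time of day could give. The labels used here give no clock time, so this stays a hypothesis, and an effect of genotype on the phase of the clock stays open and untested.

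Under cerulein 11 of 17 (12 adjusted over the list alone) duct, 10 of 14 (11 adjusted over the list alone) heat shock and 5 of 20 (9 adjusted over the list alone) actin genes were lower in Adam17ex, and 2 of the 17 duct genes higher (camera adjusted p = 3.75e-11, 8.81e-20 and 4.56e-05, with adjusted p = 0.000847, 0.000480 and 0.464 with an estimated correlation). A uniformly smaller response is argued against by 63 of 327 interaction genes that responded more in Adam17ex (one-sided exact binomial test against a false call rate of 0.05, which treats genes as independent, p = 4.00e-20). However, the interaction also carries the genotype difference under PBS, where 3 Adam17ex libraries are shallow. For these genes a larger response to cerulein is not separated from a different PBS level. In thinned counts these lists had a median of -0.82, against -0.75 at full depth, which tests only how the fit handles unequal depth. The 3 shallow libraries are PBS libraries, and mean depth was 1026610 UMIs in WT and 1164390 in Adam17ex cerulein libraries. Immediate early genes had a median of 1.01 in the same comparison, so a different time between the last injection and collection cannot be told apart from genotype, as these genes change within the hour. An effect of the Adam17 allele on the response remains a hypothesis.

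Under PBS the test called the fibroblast, endothelial and monocyte lists higher in Adam17ex, with 4 of 12 (9 adjusted over the list alone), 0 of 8 (3 adjusted over the list alone) and 0 of 10 genes called (camera adjusted p = 1.13e-10, 0.00191 and 0.0147, with adjusted p = 0.235, 0.235 and 0.709 with an estimated correlation). Their median was 0.99 in thinned counts and 0.99 at full depth, which tests only how the fit handles unequal depth. With the ribosomal share as a covariate the median was 0.89, against 0.97. That share cannot be told apart from genotype because 3 of 4 Adam17ex PBS libraries have a high one. The monocyte call was lost without Adam17ex PBS replicate 3 (median 0.25), at a mean log2 CPM of 6.39 against 3.71 to 4.76 and with an enzyme share of 29.8%, and without WT PBS replicate 3 (0.63) or 4 (0.62). A lower share of acinar cells would raise all other cell types alike, as endothelial (0.82), monocyte (0.87), adipocyte (1.13) and islet markers (0.57) go. The duct and metaplasia list had a median of 0.13 ± 0.10, against 1.07 ± 0.18 (SE) for fibroblast markers, and the B cell list had -0.58 ± 0.53. As the duct list also holds metaplasia genes, it does not measure duct cells alone and cannot decide on the acinar share. That share stays open, and more stroma in the sampled piece or in the mutant pancreas stays open and untested.

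Chance is argued against for the 4 group comparisons, each with 1 of 35 splits of its 8 libraries at the real count. This is the smallest share that 35 splits can give, and it is not corrected for several comparisons. The real count was 3388 and the highest other 4 for cerulein in WT, 2493 and 12 in Adam17ex, 799 and 4 for genotype under cerulein, and 112 and 41 under PBS. Under PBS the count moved with the setting, to 14 in a fit to the compared groups alone and 406 without sex, so the splits do not settle that difference. Over 100 drawn splits the mean effect called 3989 genes and the highest other 2636, with 1 split at the real count, which argues against chance. The interaction called 496 genes and the highest other 495, also with 1 split at the real count. The highest interaction splits kept the genotype labels of the cerulein libraries, so they carry that difference too. For this reason the splits cannot decide whether the interaction count exceeds chance.

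Single libraries stood apart from the other 3 of their group in 36 of 531 groups tested, where chance gives about 1 in 20. In Adam17ex PBS, replicate 4 held 1009630 UMIs against 455547 to 492878, and replicate 3 an enzyme share of 29.8% against 38.3% to 39.3%. On the log2 CPM scale, replicate 3 of that group stood at 3.82 for Atf3, 2.61 for Nrip3 and 2.04 for Tac1, replicate 2 at 7.14 for Btg2, 3.64 for Hbegf and 6.75 for Fgf21, and replicate 4 at 2.36 for Hspa4l. In Adam17ex cerulein, replicate 3 stood at 5.81 for the adipocyte list against 3.14 to 3.21, 4.51 for the B cell list against 1.79 to 2.17, 6.55 for the oxidative stress list, 7.91 for Cfd, 5.38 for Ighm, and 1.07 for both P2ry14 and Nrip3. Replicate 2 stood at 13.52 for the enzyme list, replicate 1 at 6.70 for the actin list and replicate 4 at 7.27 for Sel1l.

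In WT PBS, replicate 2 stood at 11.18 for Reg3b against 7.20 to 7.77, 2.87 for Relb, 6.14 for the acinar factor list and 5.96 for the autophagy list. Replicate 3 stood at 1.66 for Egr1 and 2.88 for S100g, and replicate 4 at 4.73 for Tpm4, 14.93 for Clps and 5.37 for the ribosome biogenesis list. In WT cerulein, replicate 1 stood at 6.41 for Hspa1b, 6.70 for Sdc1 and 1.59 for Adipoq, replicate 2 at 3.88 for the endothelial list, replicate 3 at 10.18 for Mt2 and 7.45 for Hmga1b, and replicate 4 at 6.23 for the autophagy list and 5.17 for Rps15a-ps2.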

How the results depend on the processing

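The settings without the 3 shallow libraries, with thinned counts and with the ribosomal share as a covariate were chosen only after the result was seen. A fold threshold of 2 left 2232 genes in WT, 1617 in Adam17ex, 459 for genotype under cerulein, 73 under PBS and 1863 for the mean effect. Thinned counts, with 5266 genes tested, left 2090, 1508, 419 and 45, with 287 for the interaction and 2449 for the mean effect. Without the 3 shallow libraries 1360 genes were called in Adam17ex, 15 for genotype under PBS and 152 for the interaction. For genotype under PBS DESeq2 called 234 (79 higher, 155 lower, against 52 and 60), no count filter 331, no sex covariate 406, a fit to the compared groups alone 14 and the ribosomal share as a covariate 21; the cause was not tested. The filter at 10 CPM in 4 libraries tested 8401 genes and was not stricter. Leaving out 1 library gave 402 to 675 genes for genotype under cerulein, 30 to 370 under PBS and 239 to 624 for the interaction. Under PBS it was 46, 72, 30 and 36 without WT PBS replicates 1 to 4, and 34, 33 and 370 without Adam17ex PBS replicates 2 to 4. With an estimated correlation 7 lists were called in WT, 6 in Adam17ex, 2 for genotype under cerulein, 0 under PBS and 3 for the interaction, and fry called 3 under PBS and 5 for the interaction. Of the main list calls, fry kept 15 of 16 in WT, 14 of 17 in Adam17ex and 5 of 6 for genotype under cerulein. It kept 2 of 6 under PBS and 5 of 9 for the interaction. Directions reversed without the shallow libraries for the islet list in Adam17ex (0.23) and in the interaction (1.10), Chga (0.019), Scg2 (0.40) and Iigp1 (0.081) in Adam17ex, and for the islet interaction with the ribosomal covariate (0.70). No clear pairing by replicate number was seen: same-numbered deviations correlated above 0.1 in 5 of 24 pairs, and 6 of 16 libraries correlated best with their own number. Between Adam17ex PBS and cerulein replicates 1 to 4 the correlations were 0.162, 5.40e-05, 0.122 and 0.240, so shared litters are not excluded. With the replicate block genotype under PBS called 501 genes without sex and 230 with it, and Xist was at -0.24 in the block without sex. Of the named genes, 74 of 96 were called in every alternative run for cerulein in WT, 66 of 106 in Adam17ex, 44 of 64 for genotype under cerulein, 4 of 28 under PBS and 27 of 49 for the interaction. Adam17 under cerulein stayed between -2.21 and -1.90 in the alternatives that tested it and was called in each.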

Other observations

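Lists of immune and dividing cells were mostly too low in this tissue to test. The 17 neutrophil markers measured held 117 UMIs in WT PBS, 54 in WT cerulein, 40 in Adam17ex PBS and 92 in Adam17ex cerulein libraries in total, and 0 of them passed the count filter. Cell cycle genes held 257, 270, 229 and 264 UMIs in the same order, with 2 of 20 tested, and mesothelial and smooth muscle markers 132, 117, 208 and 152, with 1 of 10 tested. T and NK cell markers held 145, 110, 118 and 382, with 1 of 17 tested. That gene, Trbc1, was counted 5, 9, 17 and 3 times in WT and 20, 114, 80 and 111 times in Adam17ex cerulein replicates 1 to 4. Trbc1 thus made up most of the 382 UMIs, and the remaining T and NK markers together held fewer UMIs in Adam17ex than in WT cerulein libraries. Interferon response, acinar transcription factor and sex-linked lists passed in 0 of 5 comparisons with camera. The smallest adjusted p among them was 0.081 for the interferon list in the interaction.

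Under PBS the clock output gene Tef was at 28.8 ± 5.83 CPM in WT and 88.8 ± 20.7 CPM in Adam17ex libraries, and after cerulein at 5.47 ± 2.44 and 3.40 ± 2.37 CPM (SD, n = 4). Dbp was at 5.07 ± 2.64 CPM in WT and 2.53 ± 1.28 CPM in Adam17ex cerulein libraries.

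For some lists that did not pass, the median, the mean and the camera test differed in sign. These were the digestive enzyme, autophagy and unfolded protein response lists for cerulein in Adam17ex, the monocyte and endothelial lists for cerulein in WT, the ADAM17 substrate and ribosome biogenesis lists for genotype under cerulein, the acinar factor, IL-6/STAT3, cell death and heat shock lists for genotype under PBS, and the ADAM17 substrate, sex-linked and mitochondrial lists for the interaction.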
